A study of Mus musculus with 6 samples.

How the data were processed

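RNA was sequenced from sorted CD4+CD8+ thymocytes in 3 Mettl14 floxed, CD4-Cre samples (KO) and 3 littermate control samples (WT), with Illumina TruSeq libraries per the labels' protocols. Per the submitters' processing notes, Trimmomatic 0.33, STAR 2.5.2, HTSeq and DESeq2 were used on build mm10. The counting mode, the strand setting and the annotation version are not given in the sources used here. Genes that overlap on opposite strands therefore cannot be separated with certainty, and a multi-copy gene can lose or share reads.

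The authors deposited raw counts per gene for each library and a combined table of the same counts, with gene lengths per the file headers. The authors also deposited a normalized signal, which is each count divided by 1 size factor per library. The authors' deposited log2 fold changes and their standard errors, and their adjusted p-values, come from their own DESeq2 fit. That file is named as paired, and no label says what was paired. Its 16448 fold changes were matched within 0.001 by DESeq2 with a 2-level block that sets replicates 1 and 2 apart from replicate 3, and not by a block on replicate number, which matched 4169. This block was found from the deposited fold changes and its use here was chosen after seeing the data; what it stands for is not known.

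Rows that name no gene were kept out of library sizes and tests. Reads without a feature made up 12.3% to 15.2% of counted reads per library, reads with several alignments 22.6% to 23.9% and ambiguous reads 0.653% to 0.701%. Counts in genes ranged from 29500254 to 33377056. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 17.3 or more for each pair. Of 43430 gene identifiers, 42462 matched the name table.

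Differential expression was tested with edgeR 4.0.16 (TMM, filterByExpr by group, quasi-likelihood test on group alone, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. Standard errors are the log2 fold change divided by the square root of the F statistic. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over 23 lists, with an estimated correlation and fry beside it. No list was called with an estimated correlation or by fry's test of a shift in 1 direction. Fry's test of change in either direction, which compares no list with other genes, had an adjusted p under 0.05 for 7 lists: m6A factors (0.0354), p53 targets (0.0135), pro-apoptotic (0.0422), anti-apoptotic (0.0212), double-negative (0.00286), stromal (0.00787) and NK and gamma-delta (0.00203). DESeq2 1.42.0 and limma-voom were alternatives. Shares of J segment counts were compared by exact permutation. BLAST 2.17.0 matched the called genes to reference transcripts. Lists, main tests, alternatives and the rule for naming genes were fixed before the data were examined, except where stated.

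The rule named Mettl14, Mettl3 and Trp53, up to 8 genes in each direction with the largest fold changes among calls with an average log2 CPM of at least 3 and no overlap between groups, and up to 4 members with the lowest p from each called list and from the p53, pro-apoptotic, receptor signalling, NKT and V(D)J lists. It left out from the largest changes sex-linked genes, pseudogenes, receptor segments and provisional names. It added Traj18 and Trav11 if counted. Some genes that the rule names are not reported here.

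The tests were checked on simulated data with the real means, dispersions and library sizes over 13039 genes. For KO against WT, edgeR recovered 26.9% of genes changed 1.5-fold, 67.2% changed 2-fold and 86.4% changed 4-fold, with 10 false calls among 139. DESeq2 recovered 37.3%, 76.1% and 84.8%, with 44 false calls among 196. Simulated genes vary independently, so the list tests were not checked for members that vary together.

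The remaining lists gave these camera results. The m6A writers, erasers and readers had an adjusted p of 0.173, double-positive genes 0.310, mature single-positive genes 0.310 and SOCS and cytokine receptor signalling 0.173. TCR-induced early genes had 0.863, oxidative phosphorylation genes 0.677, the unfolded protein and integrated stress response 0.439, and heat shock and dissociation stress genes 0.851. B cell markers had 0.209, thymic stromal and endothelial markers 0.276 and red cell markers 0.310. The median or mean of the stress response, heat shock and stromal lists lay below 0 while the test was upward. Cell cycle genes had 0.677, and were called downward without WT replicate 1 (2.66e-10) and upward without WT replicate 2 (0.0367) or WT replicate 3 (0.0118). B cell markers were called upward without KO replicate 1 (2.58e-07, median 0.76), without WT replicate 2 (0.0382) and with no filter on low counts (0.0187). Mature single-positive genes were called upward without KO replicate 1 (0.0016). Without WT replicate 1, double-positive genes (0.0121), SOCS and cytokine receptor signalling (0.0283) and TCR-induced early genes (0.00933) were called upward.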

Results

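Gene expression was measured by RNA sequencing in CD4+CD8+ double-positive thymocytes, the stage at which the T cell receptor alpha chain is rearranged and developing T cells are selected. The cells were sorted from the thymus of mice carrying floxed Mettl14 and a CD4-Cre transgene (KO, 3 libraries) and of littermate controls (WT, 3 libraries). Mettl14 encodes the partner of Mettl3 in the complex that writes N6-methyladenosine on RNA. Counts assigned to genes ranged from 29500254 to 33377056 per library. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries, which may be partly technical. Expression levels are TMM-scaled CPM, the counts of a gene relative to the total of its library, positions are on mm10, and log2 fold changes are KO minus WT.

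The first question was whether the targeted gene was lower in the KO libraries. Mettl14 (chromosome 3, 123364645 to 123385990) was at 55.6 ± 3.37 CPM (SD, n = 3) in WT and 39.6 ± 2.97 CPM (SD, n = 3) in KO, which is 28.7% lower, and all 3 KO libraries lay below all 3 WT libraries. The log2 fold change was -0.49 (SE 0.086), and the difference did not pass the threshold over all genes tested (edgeR adjusted p = 0.289, unadjusted p = 4.96e-04). DESeq2 gave -0.48 with an adjusted p of 0.0043, and the authors' deposited table gives -0.48 with an adjusted p of 0.00401. The labels do not say which exons were floxed, so counts over the whole gene can include RNA from outside the deleted part. Mettl3 was at 66.6 ± 1.40 CPM in WT and 62.4 ± 3.53 CPM in KO (edgeR adjusted p = 0.809), a log2 fold change of -0.096 that was -0.062 without KO replicate 1. Trp53, which encodes p53, was at 157 ± 4.30 CPM and 155 ± 2.43 CPM (edgeR adjusted p = 0.964).

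The second question was which genes changed between the genotypes. Of 13039 genes tested, 5 changed in edgeR's quasi-likelihood test, 1 higher and 4 lower in KO. Cacna1e (chromosome 1, 154390731 to 154884501), which encodes the pore-forming subunit of a voltage-gated calcium channel, fell from 92.1 ± 4.51 CPM to 42.6 ± 5.31 CPM (SD, n = 3 each), a log2 fold change of -1.11 (SE 0.10, edgeR adjusted p = 0.0122). Counts assigned to Hmga1b (chromosome 11, 120762794 to 120764419) fell from 21.2 ± 3.79 CPM to 0.538 ± 0.173 CPM. The log2 fold change was -5.30 (SE 0.26, edgeR adjusted p = 0.000176). The other calls, named after their values were seen, were processed pseudogenes. Atp6v0c-ps2 (chromosome 6, 37806086 to 37806550) had a log2 fold change of -5.82 and Gm9825 (chromosome 6, 7981829 to 7983430) of -4.13 (edgeR adjusted p = 0.000176 for both). Gm33707 (chromosome 3, 60769887 to 60770455) had 3 counts in WT and 5702 in KO, a ratio of 1995 with an exact 95% counting interval of 682 to 9675 (edgeR adjusted p = 9.77e-05).

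Hmga1b, Atp6v0c-ps2 and Gm9825 share nearly all of their sequence with other genes, so their counts are uncertain. Hmga1b matched Hmga1 transcripts at 99.8% identity, Atp6v0c-ps2 matched Atp6v0c at 99.8% and Gm9825 matched Rnps1 at 99.4%. All 3 parent genes lie on chromosome 17, between 24163866 and 27563674. Gm33707 is less alike: it matched Gm4735 at 89.5% and Eno1 at 89.2%, and Eno1 had a log2 fold change of 0.18 (edgeR adjusted p = 0.776). Counts of copy and parent added together were 44.5 ± 3.82 CPM in WT and 47.7 ± 2.74 CPM in KO for Atp6v0c, and 59.6 ± 6.50 CPM and 60.5 ± 3.98 CPM for Rnps1. For Hmga1 the sums were 89.5 ± 23.6 CPM and 98.6 ± 6.26 CPM. Parents alone were higher in KO: Atp6v0c at 36.3 ± 3.64 CPM in WT and 47.6 ± 2.79 CPM in KO, and Rnps1 at 45.2 ± 4.86 and 59.7 ± 4.08 CPM. Hmga1 was at 68.2 ± 27.3 and 98.1 ± 6.33 CPM. Lower counts of these copies therefore do not show lower expression, since the parent was higher where the copy was lower.

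In a comparison chosen after the values were seen, tested genes with an unadjusted p under 0.01 made up 4.38% of the 707 on chromosome 17 (31 genes) and 1.34% of those on the other chromosomes (Fisher's exact test over 20 chromosomes, adjusted p = 1.42e-06). Cdkn1a, Notch3, Ptcra and Ubash3a, described with their lists, are among these 31.

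**Figure D1:**
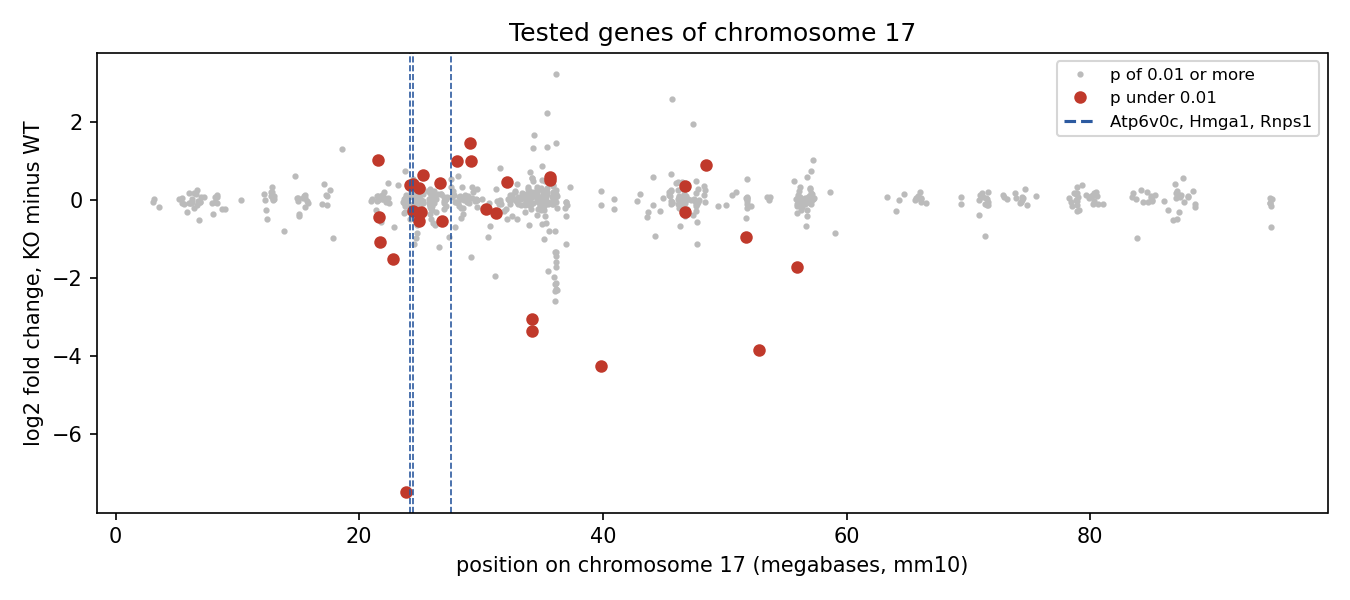
Tested genes of chromosome 17 are placed by position (horizontal axis, megabases on mm10) and log2 fold change, KO minus WT (vertical axis), with genes at an unadjusted p under 0.01 in red and dashed lines at Hmga1, Atp6v0c and Rnps1. The interquartile range of the red positions runs from 24.7 to 35.7 megabases.

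The library WT replicate 1 stood apart on the first principal component, which held 46.3% of the variance, at -23.1 against -4.00 to 11.9 for the others. Across all genes, 876 had an unadjusted p under 0.05, where 652 would be expected by chance. This excess was not stable. The count was 542 of 13234 tested genes without WT replicate 2, 608 of 13456 without KO replicate 1 and 1715 of 13425 without WT replicate 3. DESeq2 called 105 genes and the authors' deposited table lists 118, of which 38 are higher and 80 lower in KO. All 5 edgeR calls are among those 118. Of the 80 lower genes in the authors' deposited table, 21 are low genes lying opposite a far more abundant gene, against 0 of the 38 higher genes, and reads of such pairs cannot be separated without strand. The edgeR count was 8 without WT replicate 1, 23 without WT replicate 3 and 14 without KO replicate 2. Cacna1e missed the threshold without WT replicate 2 (edgeR adjusted p = 0.10), KO replicate 1 (0.147) or KO replicate 3 (0.0635). Within replicates 1 and 2 alone, which the authors' deposited fold changes set apart from replicate 3, edgeR called 6 genes, 4 of them among the 5 main calls.

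**Figure D2:**
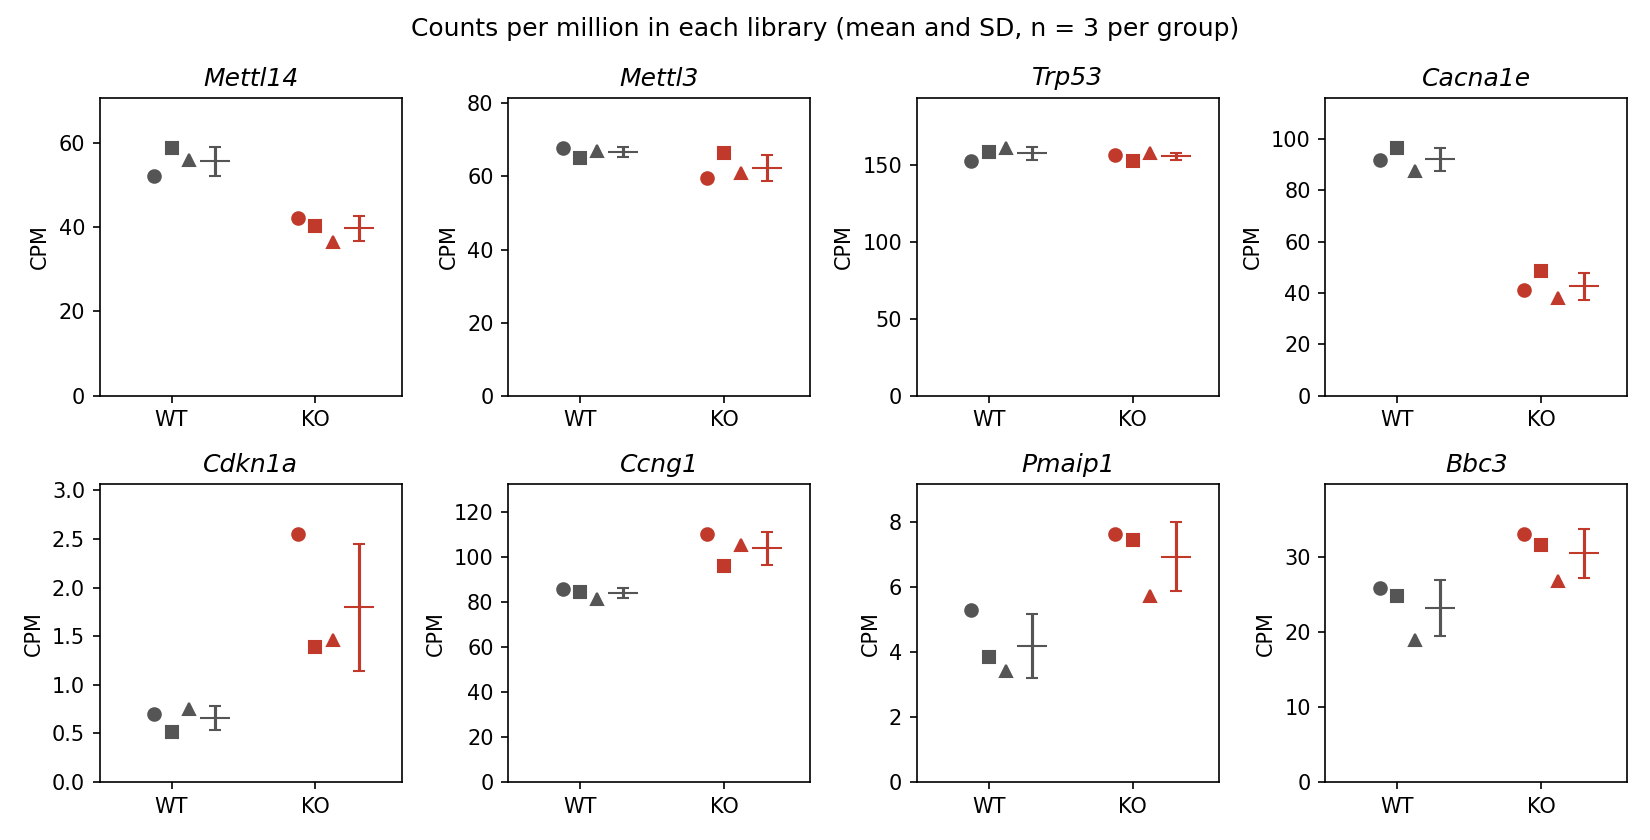
Each panel plots the CPM of a gene (vertical axis, from 0) in the 3 WT libraries (grey) and 3 KO libraries (red); marker shapes give replicate numbers 1 (circle), 2 (square) and 3 (triangle), and the bars are the mean and SD. Mettl14 and Cacna1e were lower in all 3 KO libraries, with group means of 55.6 and 39.6 CPM for Mettl14 and 92.1 and 42.6 CPM for Cacna1e.

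The series title names p53-dependent apoptosis, so targets of p53 were tested as a list fixed before the data were examined. As a group the 38 tested p53 targets were shifted upward in KO (camera adjusted p = 0.0158, and 0.539 with an estimated correlation), with a median log2 fold change of 0.10. The estimated correlation of this list was 0.0084, not above the preset 0.01, and the unadjusted camera p with it was 0.0469. Over all genes tested 0 members passed in edgeR, 0 in DESeq2 and 0 in limma-voom, and 0 passed in edgeR adjusted over the list alone. At an unadjusted p under 0.05 there were 8 members, 6 higher and 2 lower. Bbc3 and Btg2 (the latter named after its values were seen) are higher in KO in the authors' deposited table (adjusted p of 0.0265 and 0.00431). This overlap with its 38 higher genes had an adjusted p of 0.0496 by Fisher's exact test over 46 list and direction tests. That test treats genes as independent, and the deposited values come from the same 6 libraries. Cdkn1a, the cell cycle inhibitor p21, was at 0.656 ± 0.125 CPM in WT and 1.80 ± 0.654 CPM in KO, a log2 fold change of 1.45 (SE 0.34, edgeR adjusted p = 0.488). Ccng1, which encodes cyclin G1, had a log2 fold change of 0.31 (SE 0.074); Pmaip1, which encodes the BH3-only protein Noxa, of 0.72 (SE 0.22), and Sesn2 of 0.70 (SE 0.22). The camera call was lost without KO replicate 1 (adjusted p = 0.0799, median 0.036) and without the genes of chromosome 17, which include Cdkn1a (chromosome 17, 29090979 to 29100722; adjusted p = 0.0696, median 0.075 over 36 members). The median was 0.10 within replicates 1 and 2 and 0.019 in replicate 3, where 1 library stands against 1.

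Genes that promote apoptosis did not pass as a list (24 tested, camera adjusted p = 0.845); their median log2 fold change was -0.017 and their mean -0.0093, while the sign of the test was upward. The median turned positive without WT replicate 1 (0.032), KO replicate 1 (0.0012) or KO replicate 2 (0.012). Pmaip1 and Bbc3, which encodes the BH3-only protein Puma, had log2 fold changes of 0.72 and 0.39 (SE 0.14), while Bik was at -0.71 (SE 0.24). Over all genes tested 0 members passed in edgeR, 0 in DESeq2 and 0 in limma-voom, with 4 at an unadjusted p under 0.05, and 0 passed in edgeR adjusted over the list alone. In the authors' deposited table, Bbc3 has a log2 fold change of 0.41 with an adjusted p of 0.0265. Anti-apoptotic genes were shifted upward (16 tested, median 0.082, camera adjusted p = 0.00573; adjusted p = 0.569 with an estimated correlation). Over all genes 0 members passed in edgeR, 0 in DESeq2 and 0 in limma-voom, with 2 at an unadjusted p under 0.05, and 0 passed in edgeR adjusted over the list alone. Bag3 had a log2 fold change of 0.52 (SE 0.14), Bcl2 of 0.31 (SE 0.11), Mcl1 of 0.18 (SE 0.085) and Birc6 of 0.27 (SE 0.14). The median of this list was 0.053 without KO replicate 1, 0.13 without KO replicate 2, 0.17 within replicates 1 and 2 and 0.030 in replicate 3. Birc6 was at 0.14 without WT replicate 1, 0.17 without KO replicate 1, 0.49 within replicates 1 and 2 and -0.14 in replicate 3, and Mcl1 at 0.11 without WT replicate 2.

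Interferon-stimulated genes gave the lowest list p-value. Of 41 tested, 39 had a higher mean in KO, the median log2 fold change was 0.59 and the list was called upward (camera adjusted p = 8.96e-13; adjusted p = 0.569 with an estimated correlation). Over all genes tested 0 passed in edgeR, 0 in limma-voom and 7 in DESeq2, with 19 at an unadjusted p under 0.05 in edgeR; 10 passed, all higher, adjusted over the list alone. Xaf1 rose by that last measure from 15.9 ± 2.96 CPM to 27.0 ± 1.14 CPM, Rtp4 from 12.3 ± 1.69 CPM to 23.4 ± 5.66 CPM, Oas3 from 9.0 ± 1.0 CPM to 17.1 ± 4.59 CPM and Oas2, like Oas3 a sensor of double-stranded RNA, from 4.40 ± 1.15 CPM to 12.0 ± 4.90 CPM. Among the 38 genes higher in the authors' deposited table, 11 were members of this list (Fisher's exact test over 46 list and direction tests, adjusted p = 9.83e-19). That test treats genes as independent, while these members varied together (estimated correlation 0.45), so its p is too small. The deposited values come from the same 6 libraries and are not separate evidence. The groups overlapped when the list was averaged in each library: KO replicate 3 (-0.046) lay below WT replicate 2 (0.034), and the two-sided exact permutation test gave p = 0.2, where 0.1 is the smallest possible. Within the 2-level block that sets replicate 3 apart, a comparison chosen after the data were seen, they did not overlap: replicates 1 and 2 were at -0.28 and 0.034 in WT and 0.18 and 0.53 in KO, and replicate 3 was at -0.42 in WT and -0.046 in KO. Relabelling within that block gave a two-sided exact permutation p of 0.167, the smallest it allows, and with the block in the model the list had a camera adjusted p of 2.47e-16. A split of the libraries that ignored genotype gave this list a smaller camera p (1.46e-24) than the real split (3.89e-14). The mean of myeloid and B cell markers, on the same scale, was -0.72, 0.19 and -0.12 in WT and -0.69, 0.87 and 0.46 in KO (replicates 1 to 3). The median of the interferon list was 0.35 without KO replicate 2 (camera adjusted p = 5.72e-06), 0.63 within replicates 1 and 2 and 0.29 in replicate 3.

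**Figure D3:**
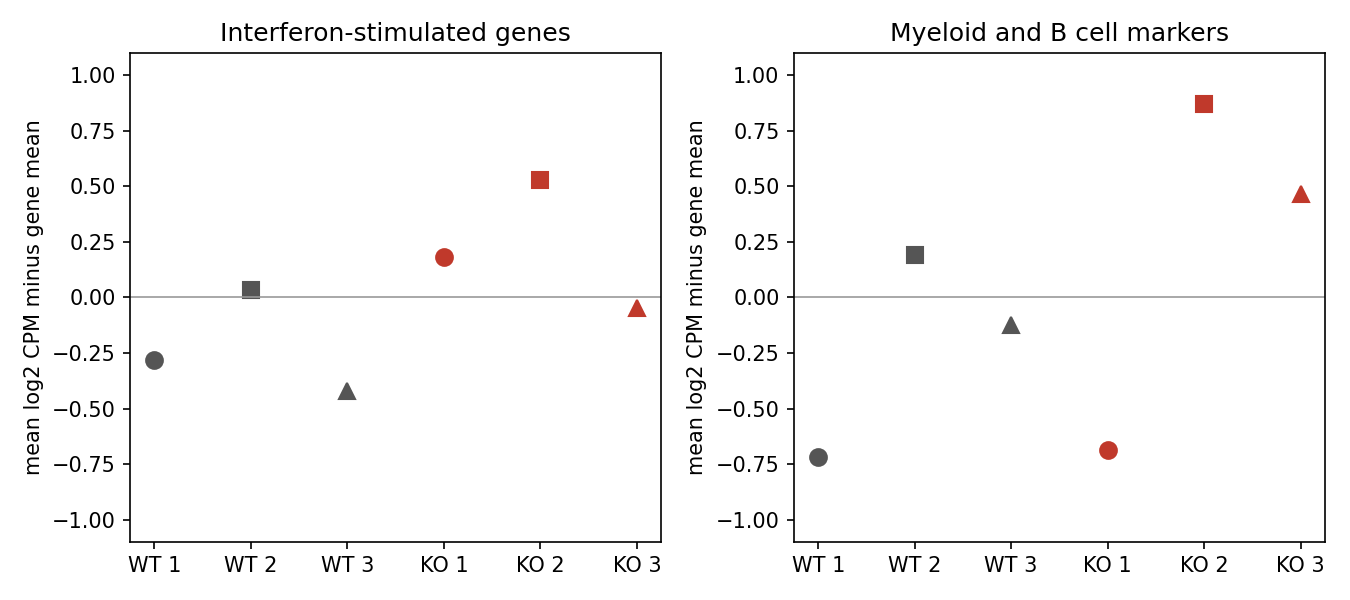
The mean log2 CPM of each list relative to its gene means (vertical axis) is plotted for each library, WT in grey and KO in red, for interferon-stimulated genes (left) and for myeloid and B cell markers (right). KO replicate 1 was at 0.18 for the interferon list and at -0.69 for the markers.

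Genes of double-negative and immature thymocytes were shifted upward (17 tested, median log2 fold change 0.35, camera adjusted p = 1.70e-04; adjusted p = 0.524 with an estimated correlation), and 5 passed, all higher, adjusted over the list alone, against 0 over all genes in edgeR, 0 in limma-voom and 2 in DESeq2, with 10 at an unadjusted p under 0.05. Tcrg-C2 and Tcrg-C1, constant regions of the gamma T cell receptor chain, rose from 0.838 ± 0.177 CPM to 2.42 ± 0.296 CPM and from 0.863 ± 0.259 CPM to 2.38 ± 0.246 CPM. These paralogs can share reads. Both are also higher in the authors' deposited table, an overlap with the 38 higher genes that has an adjusted p of 0.0201 by Fisher's exact test. That test counts the paralogs as independent genes. Ptcra, the pre-T cell receptor alpha chain, rose from 39.9 ± 2.53 CPM to 51.0 ± 3.65 CPM, and Notch3 from 98.7 ± 2.53 CPM to 136 ± 23.8 CPM. Ptcra and Notch3 lie on chromosome 17, and the list was called without that chromosome (camera adjusted p = 0.00379). NK, innate and gamma-delta lymphocyte markers were also called upward (median 0.40, camera adjusted p = 0.0116, and 0.569 with an estimated correlation). In all, 4 tested genes, Tcrg-C1 and Tcrg-C2 among them, are in both lists. Without those 4, a test chosen after the data were seen, the double-negative list had a median of 0.25 over 13 members and missed the threshold (camera adjusted p = 0.0774). With all 17 members kept, the median of the double-negative list was 0.42 within replicates 1 and 2 and 0.57 in replicate 3.

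Components of T cell receptor signalling were called upward by a small amount (44 tested, median 0.058, camera adjusted p = 0.0149; adjusted p = 0.743 with an estimated correlation), with 34 members above 0. The members with the lowest p went both ways. Ubash3a, a negative regulator of receptor signalling, had a log2 fold change of -0.35 (SE 0.089), Dusp1 of -1.21 (SE 0.52, with WT replicate 1 at 78.5 CPM and the other libraries at 14.8 to 21.4 CPM), Nfatc1 of 0.22 (SE 0.075) and Bcl10 of 0.19 (SE 0.077). This call was lost without WT replicate 2 (adjusted p = 0.236), WT replicate 3 (0.0591) or KO replicate 1 (0.0815), and the median was 0.093 without WT replicate 1 and 0.035 with upper-quartile scaling. Ribosomal protein genes were also called upward (56 tested, median 0.053, camera adjusted p = 0.0116; adjusted p = 0.78 with an estimated correlation), with Rpl13a at 0.13 (SE 0.077) and Rplp0 at 0.15 (SE 0.095). The call was lost without WT replicate 1 (adjusted p = 0.64, median 0.0077) or KO replicate 3 (adjusted p = 0.494, median 0.014). The median was 0.086 without WT replicate 3 or KO replicate 2, and 0.031 with upper-quartile scaling. Rpl13a was at 0.074 without WT replicate 1, 0.21 without WT replicate 3 and -0.028 in replicate 3, and Rplp0 at 0.057 without WT replicate 1; Dusp1 was at -0.21 without WT replicate 1.

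Myeloid and dendritic cell markers were called upward (10 tested, median 0.68, camera adjusted p = 0.0123; adjusted p = 0.569 with an estimated correlation), with H2-Ab1 at 0.48 (SE 0.16), Cd74 at 1.48 (SE 0.62), H2-Eb1 at 1.65 (SE 0.75) and Cst3 at 0.14 (SE 0.071). Cd74, abundant in antigen-presenting cells, was at 3.79 ± 1.25 CPM in WT and 10.6 ± 8.14 CPM in KO, where replicate 1 was at 2.42 CPM, below the WT mean, and replicate 2 at 18.7 CPM. Without KO replicate 2 the log2 fold change was 0.78 for Cd74 and 0.80 for H2-Eb1. The call was lost without KO replicate 2 (adjusted p = 0.0964, median 0.59) or KO replicate 3 (adjusted p = 0.0567, median 0.38), and the median was 1.09 without KO replicate 1. Without the genes of chromosome 17, 7 members were left with a median of 0.64 (adjusted p = 0.158). NK, innate and gamma-delta lymphocyte markers were called upward (11 tested, median 0.40, camera adjusted p = 0.0116, and 0.569 with an estimated correlation). They were led by Tcrg-C2, Tcrg-C1, Nkg7 at 1.30 (SE 0.55) and Fcer1g at 0.85 (SE 0.36). The double-negative list also holds Tcrg-C2, Tcrg-C1 and Fcer1g. Nkg7 was at 0.308 ± 0.078 CPM in WT and 0.763 ± 0.462 CPM in KO, with KO replicate 1 at 0.265 CPM. Fcer1g was at 0.301 ± 0.025 CPM in WT and 0.545 ± 0.158 CPM in KO. The call of this list was lost without KO replicate 3 (adjusted p = 0.287) or with a filter of 1 CPM in 3 libraries (0.0905). Its median was 0.61 without WT replicate 2, 0.72 without WT replicate 3 and 0.70 without KO replicate 1. Without the 4 genes shared with the double-negative list, 7 members were left with a median of 0.046 (camera adjusted p = 0.975), and Nkg7 was at 0.84 without KO replicate 3. In the authors' deposited table Tcrg-C1 and Tcrg-C2 give this list an adjusted p of 0.0139 by Fisher's exact test for the higher genes. That test counts these paralogs, which can share reads, as independent genes.

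**Figure D4:**
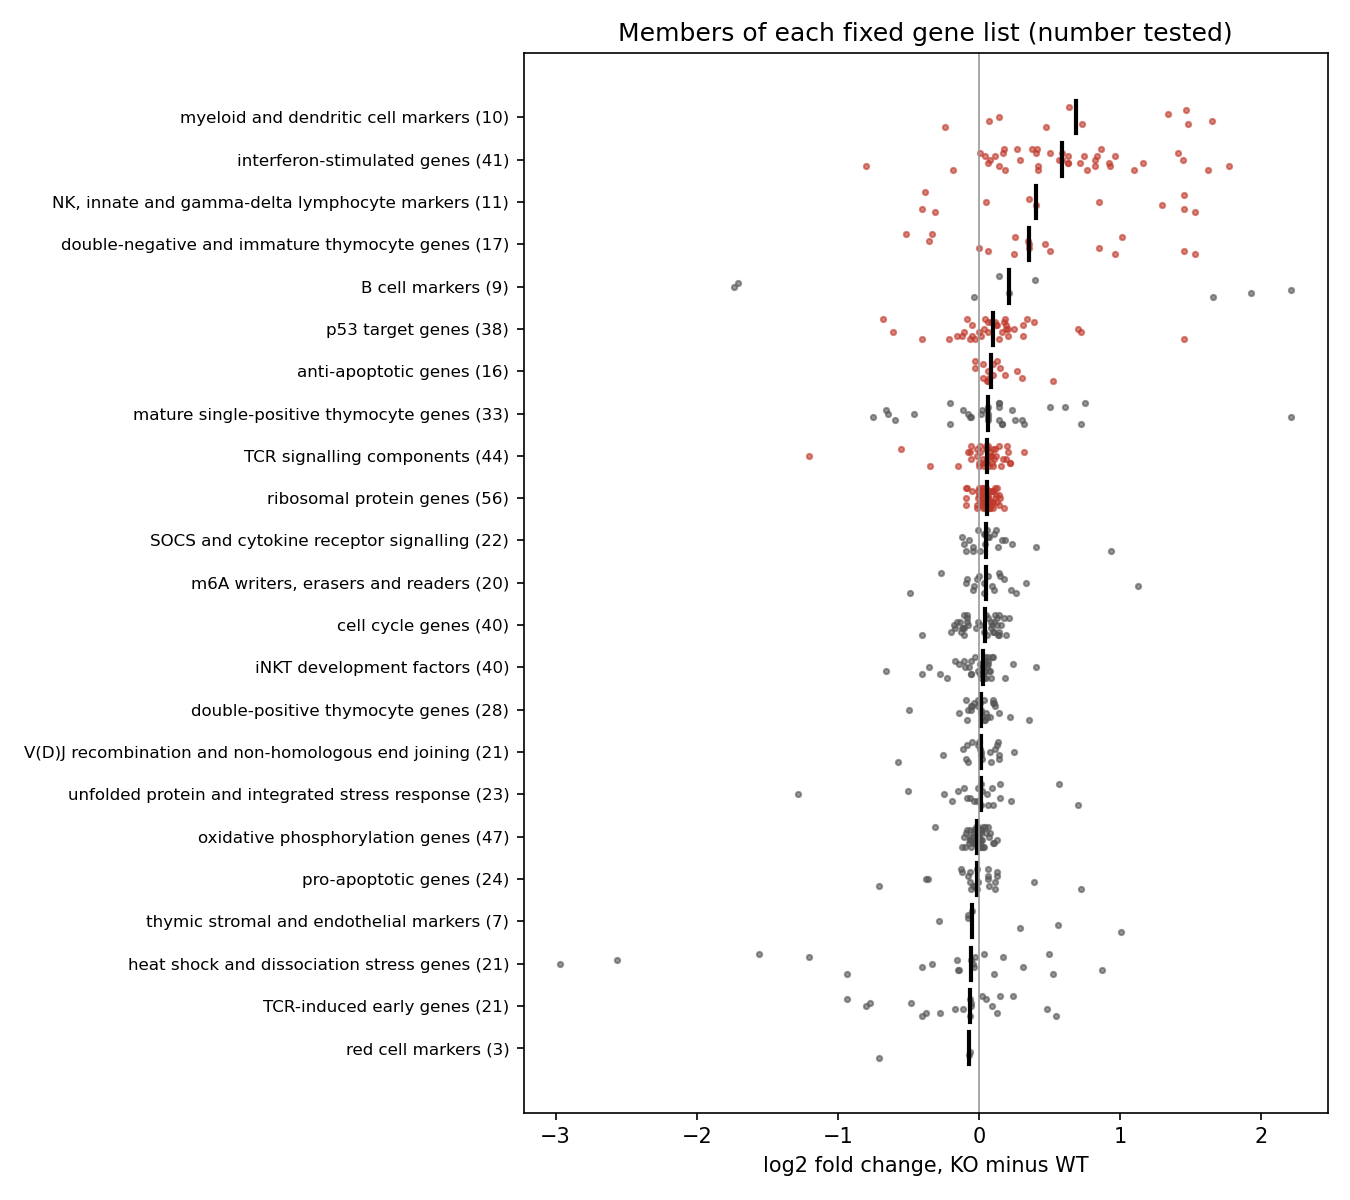
Each point is one tested gene of a fixed list, placed by its log2 fold change, KO minus WT (horizontal axis); the number tested follows each list name, the black bar is the list median, and lists called by camera are red. Medians of the 8 called lists ran from 0.053 for ribosomal protein genes to 0.68 for myeloid and dendritic cell markers.

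Factors for the development of invariant NKT cells, a T cell lineage selected from double-positive thymocytes, did not pass as a list (40 tested, median log2 fold change 0.030, mean -0.020, camera adjusted p = 0.677). The members with the lowest p were Elf4 at 0.19 (SE 0.083), Myc at -0.28 (SE 0.15), Klf2 at -0.66 (SE 0.37) and Tsc1 at -0.10 (SE 0.067). With 1 library left out the median ranged from 0.0029 to 0.064. Without KO replicate 3, Klf2 was at -1.20 and Myc at -0.44, Klf2 was at -0.42 without KO replicate 1, and in replicate 3 alone Klf2 was at -0.081 and Myc at 0.082. Genes of V(D)J recombination and end joining did not pass either (21 tested, median 0.014, mean -0.0068, camera adjusted p = 0.677). Rag2, a subunit of the recombinase, was at 0.14 (SE 0.069), Dclre1c at 0.14 (SE 0.078), Nhej1 at 0.25 (SE 0.14) and Poll at -0.57 (SE 0.24). The median ranged from -0.0063 (without KO replicate 1) to 0.052 (without KO replicate 2) with 1 library left out and was -0.0090 with upper-quartile scaling, and Nhej1 was at 0.16 without KO replicate 1.

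Invariant NKT cells use the J segment Traj18, and J segments far from the V genes are reached by later rearrangements, so J segment use was compared. Segments Traj1 to Traj30 took 51.3 ± 8.50% of Traj counts in WT and 39.9 ± 10.8% in KO (SD, n = 3 each), a difference of -11.4 percentage points that was not separated from the spread between libraries (two-sided exact permutation p = 0.3, smallest possible 0.1). It was -6.61 without KO replicate 1, -7.05 without WT replicate 1 and -17.2 without KO replicate 2, and -14.5 within replicates 1 and 2 against -5.20 in replicate 3. Counts over all 59 segments ranged from 958 to 1377 per library. The share ran from 43.0% (95% Wilson interval 40.1 to 45.9) in WT replicate 3 to 60.0% (57.4 to 62.5) in WT replicate 1, and from 30.4% (27.7 to 33.2) in KO replicate 1 to 51.6% (48.8 to 54.4) in KO replicate 2. Intervals cover counting error only. Traj18 had 10, 6 and 2 counts in WT and 6, 6 and 2 in KO, and Trav11 had 0 counts in every library.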

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

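The 2-level block, the fits within replicates 1 and 2, and the list tests without chromosome 17 or without shared members were chosen after the data were seen. The cause of a shift was not tested, except where it is named. The count of changed genes was 5 in edgeR and 5 with the replicate block, with DESeq2 size factors, with upper-quartile scaling and with gene length offsets. It was 30 with no filter on low counts, 105 in DESeq2 and 115 in DESeq2 with the 2-level block, and leaving out 1 library gave 4 to 23. Mettl14 was lower under every alternative; it passed the threshold in DESeq2 (-0.48) and in DESeq2 with the 2-level block (-0.48), and ranged from -0.53 to -0.43 with 1 library left out.

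Same-numbered libraries did not deviate together for replicates 1 and 2, with correlations of their deviations of -0.34 and -0.11, but did for replicate 3 (0.36). The highest correlations crossed the numbers: 0.47 for WT replicate 1 with KO replicate 2, and 0.37 for WT replicate 2 with KO replicate 1. The replicate numbers had not been taken as pairs in the main fit, since no label says what was paired. A pairing or batch that does not follow them remains possible. The replicate block left 5 genes and 8 lists called, gave the p53 list an adjusted p of 0.0077, and gave the J segment difference of -11.4 points a sign-flip p of 0.5.

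Of the 8 called lists, 0 were called with an estimated correlation and 0 by fry in 1 direction. Over all 23 lists, 4 were called within replicates 1 and 2, and 5 to 11 with 1 library left out, which include lists outside those 8. The p53 list had an adjusted p of 0.539 with an estimated correlation, 0.188 by fry, 0.0696 without chromosome 17, where fewer members are tested, and 0.0083 to 0.0799 with 1 library left out. The interferon and anti-apoptotic lists were called under every alternative with the preset correlation. The double-negative list was too, except without the 4 genes it shares with the NK and gamma-delta list (0.0774), and that list was then at 0.975.

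Lists that were not called changed direction as follows, with adjusted p. TCR-induced early genes turned upward with the replicate block (0.945), upper-quartile scaling (0.957), no filter (0.94) and the 2-level block (0.917). They also did without WT replicate 1 (0.00933) or KO replicate 1 (0.258), and stayed downward on leaving out each of the other libraries (0.151 to 0.732). Pro-apoptotic genes turned downward by fry (0.958), and mature single-positive genes within replicates 1 and 2 (0.823). Oxidative phosphorylation genes turned upward with no filter (0.834) and within replicates 1 and 2 (0.823). Heat shock genes turned downward at 1 CPM in 3 libraries (0.931) and without chromosome 17 (0.875), and red cell markers upward with no filter (0.852). With 1 library left out, ranges were 0.0894 to 0.878 for NKT factors, 2.66e-10 to 0.962 for cell cycle genes, 0.0609 to 0.870 for oxidative phosphorylation and 0.204 to 0.988 for heat shock genes. Trp53 ranged from -0.039 to 0.0059 (log2). At this depth, genes near 1 CPM such as Cdkn1a rest on few counts.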

Other observations

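The tests of chromosome 17 and of antisense genes, the test that left out WT replicate 1 and the tests within the 2-level block were chosen after the results were seen; the marker covariate, the exact test of the interferon list and the counts over other splits were set before theirs. In the 10 splits of the 6 libraries into groups of 3, the real split called 5 genes and the highest other called 0, so 1 split reached that count. The real split called 8 lists and the highest other 9, so 2 splits reached that number. For the p53 list the real p was 0.0055 and the lowest other 0.0593, and 1 split gave a p as small. With 10 splits no share under 0.05 can be reached.

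Genes with an unadjusted p under 0.01 were concentrated on chromosome 17, at 4.57% of its tested genes against 1.34% elsewhere when H2 genes were left out. A segment of chromosome 17 that differs by strain between the KO and WT animals may account for the excess: the interquartile range of their positions was 11 megabases against a median of 24.0 in random draws (permutation p = 0.0289). The draws treat genes as independent, so neighbours that vary together could also lower this p. The range was computed for the real split alone. Hmga1, Atp6v0c and Rnps1, the parents of 3 called copies, lie nearby, and their log2 ratios, KO over WT, were 0.52, 0.39 and 0.40 alone but 0.14, 0.10 and 0.022 with the copy's counts added. For Atp6v0c (sums of 44.5 ± 3.82 CPM in WT and 47.7 ± 2.74 CPM in KO) and Rnps1 (59.6 ± 6.50 and 60.5 ± 3.98 CPM), the copy fell and the parent rose. The sums stayed within their SD, which argues against loss of Mettl14 acting through other genes on these copies and parents. Hmga1 varied too much in WT (SD 27.3 CPM) to say. For the excess on chromosome 17 as a whole, loss of Mettl14 acting through other genes cannot be told apart from such a segment, since both go with genotype. Of the 10 splits 1, the real one, had an odds ratio as large as 3.52 (95% interval 2.30 to 5.24), and the highest other was 2.80. Genotypes of the animals were not analysed here, and Cdkn1a, Notch3 and Ubash3a lie within that region.

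The interferon list may be higher in KO for several reasons. The library WT replicate 1 alone does not account for the size of the median, which was 0.49 without that library and 0.59 with it. The camera adjusted p was then 1.51e-08, but camera also called this list in 4 of the 9 other splits, so that call excludes little. Without KO replicate 2 the median was 0.35 and the camera adjusted p 5.72e-06. Myeloid and B cells carried into the KO libraries cannot be told apart from other causes: with their marker mean as a covariate the median went from 0.59 to 0.42 and the list was still called (adjusted p = 1.72e-09), which had been set beforehand as evidence against them, but 4 of the 9 other splits also called this list, so that bound was too lenient. Loss of Mettl14 cannot be told apart from chance. Full separation of the KO from the WT libraries had been set beforehand as its mark, and an overlap as evidence against it. Over all 6 libraries the groups overlapped by 0.080 (exact permutation p = 0.2), so by that bound the result counts against loss of Mettl14. It is left open here only because the overlap was under the pooled SD of 0.26, a limit that was not part of the prediction. Within the 2-level block of replicates the groups separated by 0.15 in replicates 1 and 2 and by 0.37 in replicate 3. The exact permutation p there was 0.167, the smallest that 12 relabellings allow. The sort for double-positive cells would remove most other cells, and 10 of the 27 myeloid markers passed the filter on low counts.

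Low genes that lie opposite a far more abundant gene were lower in KO: 173 such genes had a median log2 fold change of -0.48, and 144 were below 0. Genomic DNA would lower genes without such a partner as much, and those had a median of -0.098 matched on expression and -0.093 matched on length too, which argues against it as the whole cause. Reads from the opposite strand of the abundant gene may account for the difference, but no test here sets them apart from other causes. Random draws of matched genes without a partner gave a permutation p of 1e-04, the smallest possible. That compares genes with and without a partner, which any cause tied to the partner predicts, and it treats genes as independent. Unspliced RNA of the abundant genes cannot be told apart: the share of reads without a feature, which holds intron reads, was 14.7 ± 0.667% in WT and 13.2 ± 0.970% in KO (n = 3 each, exact permutation p = 0.2, smallest possible 0.1). Loss of Mettl14 cannot be told apart either, since WT replicate 3 (-0.34) lay at the level of KO replicate 2 (-0.34) and the exact permutation p was 0.2, while within the 2-level block the groups separated by 0.50 in replicates 1 and 2 and by 0.083 in replicate 3 (exact p = 0.167, the smallest possible).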
